A study of Homo sapiens with 6 samples.

How the data were processed

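The samples were total RNA of 3 oral squamous cell carcinoma cell lines, each as control and as cetuximab-resistant cells, 6 arrays in all. Per the labels' protocols, RNA was isolated with a phenol-based reagent and a column kit, amplified and labelled with Cy3 as cRNA. Each array holds 62976 spots, of which 58717 are not controls, for 50599 probes of 60 bases; 902 probes have 10 spots and the others 1. The deposited scanner tables give for each spot an intensity on a linear scale, per the file headers made with Agilent Feature Extraction 10.7.1.1, while the submitters' processing notes name version 9.5.1.1. Their processed signal is already corrected for background by that software. All 6 arrays carry the same slide identifier, so slide could not be tested as a batch. The series' value table holds the authors' processed values of the same arrays, 1 intensity per probe on a linear scale. Its columns hold the same sorted values, as after quantile normalization, with a median of 15.7, and correlate on the log2 scale with the scanner values at 0.993 or more, and it was used as an alternative; the authors' steps to its scale are not given in the sources used here.

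The log2 of the processed signal was taken per spot, spots flagged as outliers (250 to 389 per array) were left out, spots of a probe were averaged, and each array's 75th percentile over non-control probes was subtracted. No non-control spot was saturated. A probe had to be well above background, as the files flag it, on at least 3 of 6 arrays, and each gene was represented by its passing probe with the highest mean; 4443 genes had more than 1 passing probe, and the text says where probes of a named gene disagree in sign. Probes were named through the RefSeq gene table of assembly GRCh38, by accession (28174 probes), current symbol (2618) or a unique synonym (620), and 19187 kept the name in the files. Coordinates are those of the files (GRCh37). The 237 probes of Y-linked genes and of XIST and TSIX were left out. This left 18508 genes, 14400 of them with a symbol.

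Resistant and control cells were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with cell line as a block, since control and resistant samples of a line share their origin, and Benjamini-Hochberg adjustment over all genes. The residual degrees of freedom were 2 per gene and the prior added 3.42. Deviations from the group means of arrays of the same line correlated at 0.615 (Sa3), 0.464 (SAS) and 0.281 (HSC3) across genes, and those of different lines all correlated below 0. Deviations from a group mean sum to 0, which draws the latter below 0, so only the former bear on the pairing. Exact tests cannot pass 0.05 here: the smallest two-sided p is 0.25 for an exact sign-flip test of 3 pairs and 0.1 for an exact permutation test of 3 against 3. Nothing says how many cultures stand behind an array, so p-values measure the spread between lines. Within a line there is 1 array per condition and no test. There, a gene not well above background on 1 array is given as at least N-fold, against the higher of its own value and the lowest value of any probe well above background on that array. Across lines the same is done for group means when a gene was well above background on no array of a group, or, in the lower group, on part of its arrays, which then take the higher of their value and that floor. A gene well above background on part of the arrays of both groups is given no fold. Genes were ranked on measured values without these bounds. The bounds hold for the background treatment used here and can exceed the difference found under another. The number of arrays limits the precision.

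The 39 gene lists (814 names, 718 tested) were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. They were tested with limma camera, which sets a list's genes against all other genes, at a preset correlation of 0.01. An estimated correlation and fry were alternatives, and p-values were adjusted over the 39 lists. Within a line, a list's median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Genes named across lines are EGFR and the 12 highest and 12 lowest symbols by mean difference among genes at least 2-fold changed in one direction in every line. No gene passed 0.05, so that part of the rule named none. Within each line the 5 highest and 5 lowest symbols and up to 3 bounds each way are named, and of each list described up to 4 members with the largest differences or those passing adjusted over the list alone.

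The gene test was tested on simulated data of 18508 genes with the observed prior variance. With 200 changed genes per simulation it found 58.8% of those changed by 4 log2 units and 0.4% of those changed by 2 at adjusted p 0.05. With 2000 changed genes it found 92.9% and 42.1%. In 20 simulations with 1 list shifted by 1 log2 unit, camera found that list in all 20 and called 1 of 760 other lists. Simulated genes vary independently, so this says nothing of correlated genes.

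Alternatives were quantile normalization, median centring, normexp background correction (offset 50) of the raw signals, the authors' values, a filter on all 6 arrays or none, flagged spots kept, the mean of a gene's probes, no block or a random block for cell line, a trended or robust prior, leaving out each line, and adjusted p 0.1. Chosen after seeing the data were scaling on 7 bright spike-in probes and on the 75th percentile of probes well above background on all 6 arrays. Spike-in scaling assumes that equal amounts of RNA were labelled. Settings that changed the values or the filter chose a gene's probe anew, except the authors' values, which kept the probe used here.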

Results

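Gene expression was measured in 3 human oral squamous cell carcinoma lines, Sa3, SAS and HSC3. Each line was measured once as control cells and once as cells made resistant to cetuximab, a therapeutic antibody that binds the extracellular part of EGFR, the epidermal growth factor receptor. The labels do not say whether cetuximab was present at harvest, nor its dose or duration. The series asks which genes go with resistance. The 6 samples gave 6 single-colour oligonucleotide arrays, 3 control and 3 resistant, with 1 array per line and condition. The 3 lines are the replicates, so a difference within 1 line had no replicate check. Between 46.9% (HSC3) and 54.3% (Sa3) of the probes were well above background on the control arrays, and between 38.7% (HSC3) and 48.5% (Sa3) on the resistant arrays. In each line the resistant array was dimmer. Its 75th percentile of signal lay -0.75 (Sa3), -1.89 (SAS) and -1.05 (HSC3) log2 units from that of the control, while the spike-in probes added to each labelling reaction changed by -0.16, 0.11 and -0.24. Values are log2 intensities relative to each array's 75th percentile, so every difference given here is relative to that point, and the median gene lay 0.25 log2 units higher in resistant cells on this scale.

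EGFR itself, the target of cetuximab, had a mean level of 3.40 ± 0.27 (SD, n = 3 lines) in control cells and 4.46 ± 0.73 in resistant cells. Its probe lies on chromosome 7 at 55274841 to 55274900 (GRCh37). The difference was 0.52 in Sa3, 0.75 in SAS and 1.89 in HSC3, a mean of 1.05 ± 0.43 (SE), and did not pass the test (limma adjusted p = 0.181). Of the other 2 EGFR probes, 1 had a mean difference of 2.63 and 1 of -0.51, so the direction depended on the probe. The EGFR ligand AREG (amphiregulin) had levels of 3.80 in control and 6.32 in resistant cells, a difference of 2.52 ± 0.50 (SE). TGFA differed by 1.84 and EREG by 1.33, with EREG at 0.050 in Sa3. NRG1, a ligand of the related receptors ERBB3 and ERBB4, had a mean difference of -2.06, with the opposite sign in both its other probes. Its value was 0.75 after quantile normalization, where its probe was chosen anew, and -2.39 in the authors' values, which kept the probe. Of 10 measured genes of the EGFR family and its ligands, none passed adjusted p 0.05 over all genes. Adjusted over the list alone, 2 were higher (AREG and TGFA) and 1 (NRG1) was lower on this scaling, and the list as a whole was not called (median 0.73, limma camera, adjusted p = 0.539). When arrays were scaled on spike-ins, the mean EGFR difference turned to -0.078.

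**Figure D1:**
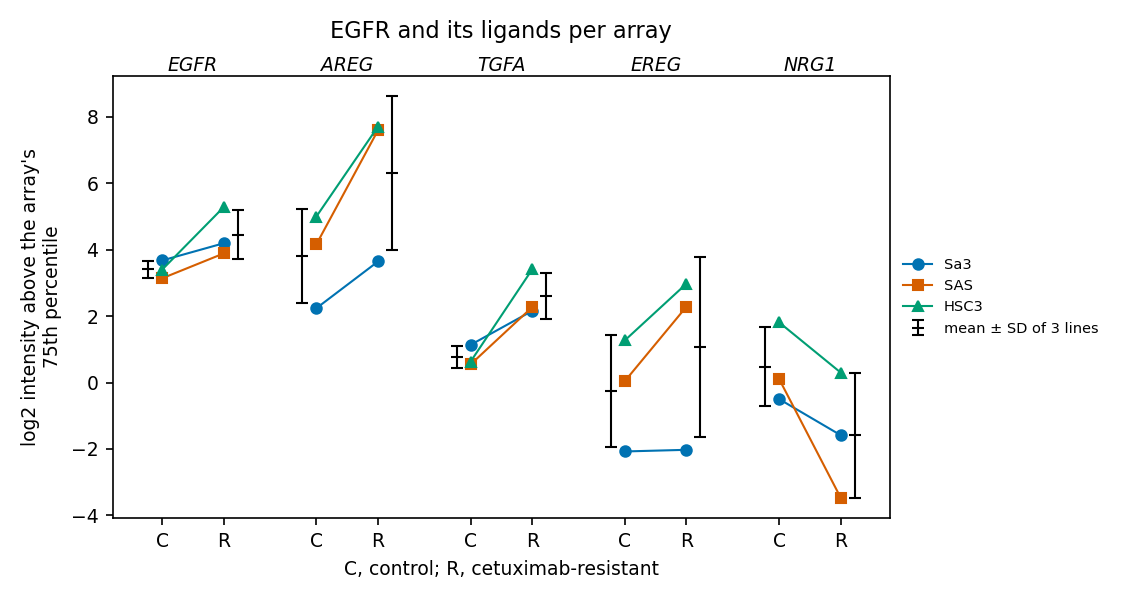
Levels of EGFR and of 4 ligands of its receptor family on each of the 6 arrays, in log2 intensity relative to the array's 75th percentile; lines join the control (C) and resistant (R) array of a cell line, and black bars are the mean ± SD of the 3 lines. AREG went from a mean of 3.80 to 6.32 and NRG1 from 0.48 to -1.59.

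The first comparison asked which genes differed between resistant and control cells in the same way in all 3 lines. The highest mean difference belonged to TXNIP, thioredoxin-interacting protein, a thioredoxin-binding arrestin that limits glucose uptake. Its level was 0.27 ± 1.84 (SD, n = 3 lines) in control and 8.02 ± 0.42 in resistant cells, 215-fold higher (38.8-fold in Sa3, 475-fold in SAS and 541-fold in HSC3). The probe lies on chromosome 1 at 145442447 to 145442506. CD274, which encodes the immune checkpoint ligand PD-L1, was at least 22.7-fold higher (chromosome 9, 5468310 to 5468369), and its second probe had a mean log2 difference of 4.07. The cytokine gene CSF2 was 21.9-fold higher, the acute-phase gene SAA2 22.3-fold and the secreted protein gene SRPX2 21.2-fold. PHLDB2 was at least 26.7-fold, LINC00520 at least 7.31-fold and HLA-DRB5 at least 11.9-fold higher; C10orf105, well above background on 1 control and 2 resistant arrays, is given no fold. After normexp background correction, which adds an offset and shrinks differences of dim probes, the mean log2 difference was 2.97 for CD274 (4.96 without it). It was 2.93 for PHLDB2 (5.48), 2.16 for C10orf105 (4.46), 1.79 for LINC00520 (4.37), 2.47 for HLA-DRB5 (4.25) and 2.86 for NEDD9 (4.98). HLA-DRB5 was driven by HSC3 (9.51 log2 units, against 1.31 in Sa3 and 1.93 in SAS), and its probe is uncertain because class II paralogs are near-identical. NEDD9 (at least 19.2-fold), OSMR (29.6-fold) and DDRGK1 (19.1-fold) each had another probe with the opposite sign, at -0.59, -0.31 and -0.79. After quantile normalization DDRGK1 was at -0.87 and after normexp background correction at -0.94, but there its probe was chosen anew. In the authors' values, which kept the probe used here, it was at 4.01.

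At the low end, BDH1, an enzyme of ketone body metabolism, was at least 20.2-fold lower in resistant cells (2.28 ± 0.88 in control, -2.96 ± 1.31 in resistant). KRCC1 was at least 13.9-fold lower, TMIE at least 12.1-fold, the arginine methyltransferase gene PRMT6 at least 9.77-fold, BEX2 at least 21.7-fold and HOMEZ at least 8.87-fold. The lysosomal membrane protein gene LAMP3 was at least 17.9-fold lower, the acyl-CoA dehydrogenase gene ACADSB at least 8.06-fold and the keratinocyte lipid transporter gene ABCA12 20.4-fold. A second ACADSB probe had a mean log2 difference of only -0.87, so that bound holds for 1 probe. After normexp correction ACADSB was at -2.04 (from -4.38). BCDIN3D was at least 11.7-fold and the transcription factor gene KLF3 at least 12.4-fold lower. PCF11, a factor of pre-mRNA cleavage and transcription termination, was not well above background on any resistant array and was at least 7.70-fold lower. These bounds depend on the background treatment. After normexp correction the mean log2 differences were -3.18 for BDH1, -2.80 for KRCC1, -2.44 for TMIE, -2.39 for PRMT6, -2.35 for HOMEZ and -1.73 for PCF11 (from -5.24, -5.08, -5.05, -4.66, -4.62 and -4.52). Of these 12 genes, 8 were well above background on 1 resistant array, LAMP3 and KLF3 on 2, and ABCA12 on all 3. Of these 24 genes, HLA-DRB5 (limma adjusted p = 0.167), CSF2 and SRPX2 (both 0.102) did not pass 0.1, and the others lay between 0.0956 and 0.0972, past 0.1 but not 0.05. No gene passed 0.1 after quantile normalization (smallest adjusted p 0.130), in the authors' values (0.134), with the mean of a gene's probes (0.101), without the cell line block (0.120), without Sa3 (0.174) or without SAS (0.294).

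**Figure D2:**
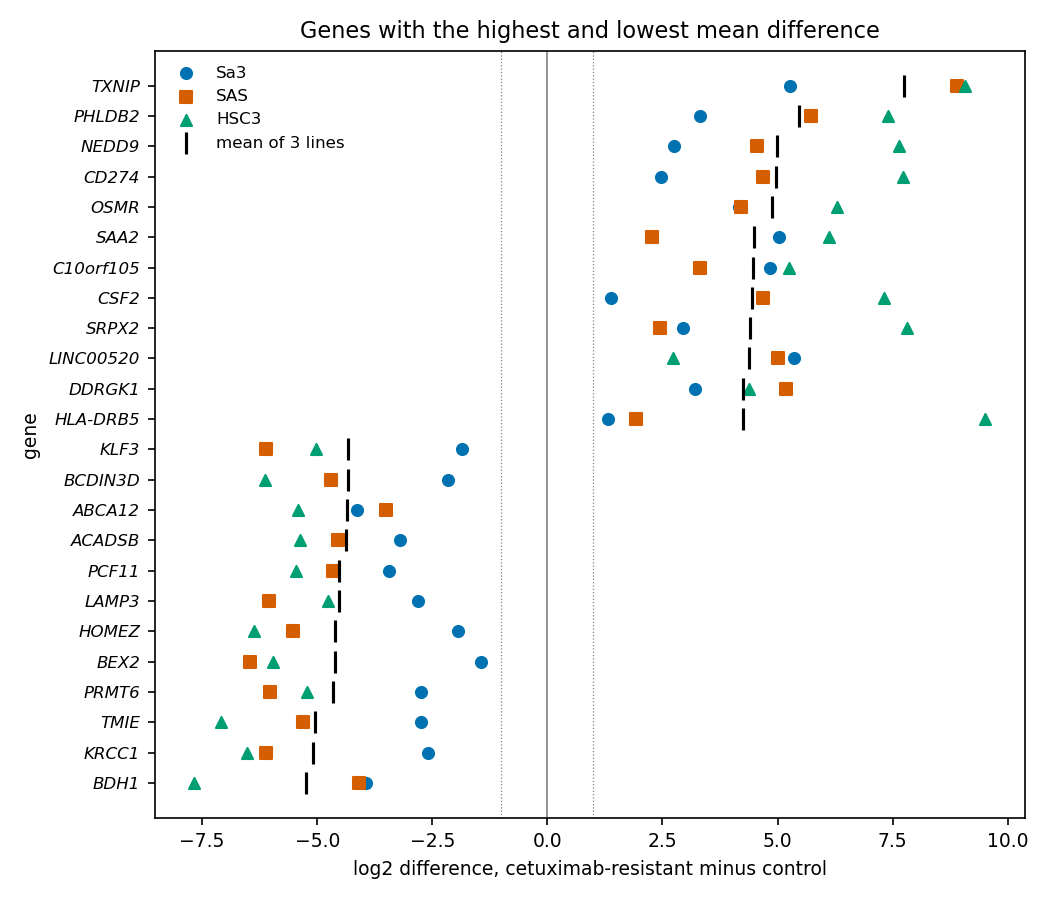
Log2 difference between the cetuximab-resistant and the control array of each line (symbols) and the mean of the 3 lines (black bar) for the 24 genes with the highest and lowest mean among genes changed at least 2-fold in one direction in every line; dotted lines mark 2-fold. TXNIP has the highest mean, 7.75, and BDH1 the lowest, -5.24.

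Of 18508 genes tested, none passed an adjusted p of 0.05 in limma with cell line as a block, while 5286 had an unadjusted p under 0.05 (3194 higher, 2092 lower). At adjusted p 0.1, 646 genes were higher and 624 lower in resistant cells. These counts were 0 and 0 after quantile normalization, in the authors' values, with the mean of probes, without the block, and without Sa3 or SAS, and 86 and 84 without HSC3. They were 211 and 1745 after median centring, 284 and 638 with the 75th percentile of detected probes, 218 and 4588 on spike-in scaling and 2494 and 1493 after normexp correction. With the filter on all 6 arrays they were 1661 and 743, with no filter 13810 and 2004, and with the random block 2262 and 1570. With cell line as a random block, 389 were higher and 493 lower at 0.05. By size alone, 1034 genes were at least 2-fold higher and 871 at least 2-fold lower in every line. Independent lines with the same shares would give 208 and 79.4, and turning the labels within 1 pair gave at most 79 higher and 86 lower. The higher genes made up 54.3% of these, but 37.1% after quantile normalization, 12.7% after median centring, 44.9% after normexp correction and 2.60% on spike-in scaling, and 67.0% with the filter on all 6 arrays and 84.3% with no filter.

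Genes of class I antigen presentation were higher in resistant cells (limma camera, adjusted p = 0.000432; adjusted p = 0.901 with an estimated correlation, as for each of the 10 lists called), with 14 of 16 members higher in every line and a median difference of 1.75. Among them were HLA-F at 5.29-fold, HLA-B at 4.65-fold, HLA-E at 4.59-fold and HLA-C at 3.69-fold. The light chain gene B2M was 2.86-fold and the peptide transporter gene TAP1 4.58-fold higher. HLA genes share long stretches of sequence, so their probes may overlap in what they measure. The HLA-C probe (chromosome 6, 31321644 to 31321703) overlaps in position the HLA-B probe (31321653 to 31321712). Its value thus cannot be taken as a separate measure of HLA-C. The counts of members may hold that locus more than once. None of the 16 passed adjusted p 0.05 over all genes, and 11, all higher, passed adjusted over the list alone. NF-kB and inflammatory cytokine genes were also higher (adjusted p = 0.00199; median 1.80), with 14 of 27 higher in every line and none lower in every line. With no filter on low signals the list was not called (adjusted p = 0.186). They included SAA1 (8.80-fold), ICAM1 (7.90-fold), LIF (at least 8.03-fold) and TNF (well above background on 2 of 3 arrays in each group, so without a fold). Adjusted over the list alone, 5 were higher. The leukocyte markers, fixed as signs of other cells, had a median of 1.22 (adjusted p = 0.0617) and were called higher under 5 of the 6 other scalings (adjusted p 0.0149 to 0.0369) and without Sa3 (0.0298). Of these, PTPRC was well above background on 1 resistant array.

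Genes of mitosis were higher (adjusted p = 0.00199; median 1.78), with 18 of 32 higher in every line. The kinesin gene KIF20A was at least 9.05-fold higher, but its mean log2 difference fell to 2.07 after normexp correction (3.33 without it). CDK1 was 6.59-fold, BUB1 6.46-fold and DLGAP5 6.38-fold higher, and no mitosis gene passed adjusted over the list alone. Most of the size came from HSC3, where CDK1 differed by 5.43 against 1.27 in Sa3 and 1.47 in SAS. Without HSC3 the list was not called (adjusted p = 0.165). Replication-dependent histone genes were higher (adjusted p = 0.00354; median 1.15), with 11 of 17 higher adjusted over the list alone, among them H2BC21 (5.18-fold), H1-2 (4.99-fold) and H2BC11 (3.99-fold). After normexp background correction the histones were not called (adjusted p = 0.144). Heat shock and immediate early genes were higher (adjusted p = 0.00806; median 1.36). HSPA1A (15.6-fold) and HSPA1B (12.9-fold), inducible HSP70 genes whose near-identical transcripts are not separated with certainty, led this list, and HSPB8 was at least 4.82-fold higher. FOS differed by 6.71 in SAS, 1.81 in HSC3 and -0.37 in Sa3. EGR2, another immediate early gene, was not well above background on any resistant array and was at least 1.23-fold lower. Adjusted over the list alone, 8 of 20 were higher and 1 was lower, and without SAS the list was not called (adjusted p = 0.0874). Matrix proteases and their inhibitors were higher (adjusted p = 0.0423; median 1.47). The urokinase receptor gene PLAUR was 10.3-fold, PLAT 7.10-fold and PLAU 6.68-fold higher, TIMP3 had a mean difference of -3.30, and 5 of 23 were higher adjusted over the list alone. Without SAS (adjusted p = 0.166) or without the cell line block (0.0661) this list was not called. With no filter on low signals the mitosis (adjusted p = 0.204), histone (0.228), heat shock (0.268) and protease (0.570) calls were lost.

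Genes of the ATF4 and amino acid response were lower (adjusted p = 0.00199; median -0.87), with 9 of 22 lower and 2 higher in every line. CBS, of cysteine synthesis, was 15.1-fold lower, CHAC1 4.99-fold, the pseudokinase gene TRIB3 4.09-fold and DDIT3 (CHOP) 3.17-fold, and these 4 passed adjusted over the list alone. NUPR1 differed by 0.44 in Sa3, 0.43 in SAS and -9.22 in HSC3, and ATF3 was 4.28-fold higher. Endoplasmic reticulum chaperone genes were lower (adjusted p = 0.00199; median -0.60), with HSPA5 (BiP) 4.93-fold, CRELD2 6.11-fold, SEL1L 3.75-fold and HYOU1 3.03-fold lower; these 4 of 18 passed adjusted over the list alone. Without Sa3, where their median was -1.40 against -0.14 in SAS and -0.10 in HSC3, the chaperones were not called (adjusted p = 0.0549). Ribosomal protein genes (median 0.67, adjusted p = 0.00199) and glycolysis genes (median 0.69, adjusted p = 0.0457) were slightly higher, with RPS12 at 2.26-fold and ENO2 at 2.83-fold, and no member of either passed adjusted over the list alone. The ribosomal median turned to -0.21 after quantile normalization and in the authors' values, to -0.46 on spike-in scaling and to -0.0037 after median centring. The list was called in 2 of the 6 other scalings, and was lost after normexp correction (adjusted p = 0.144), on spike-in scaling (0.0624) and without SAS (0.0874). The glycolysis call was lost under each of the 6 other scalings and without any 1 of the lines (adjusted p 0.0554 to 0.103), and its median turned to -0.44 on spike-in scaling and was 0.021 after median centring. With no filter both calls were lost (adjusted p = 0.518 for ribosomal and 0.863 for glycolysis genes). The medians of the other 8 lists kept their sign under all 6. The calls were made with camera at a preset correlation between genes, and all were lost with an estimated one. For histone and ATF4 genes the estimate (0.0026 and 0.0061) lay below the preset 0.01, so a higher correlation does not account for their loss. For the other called lists it lay above, from 0.046 (glycolysis) to 0.95 (mitosis). With an estimated correlation camera's test rests on the 2 residual degrees of freedom, so hardly any list could pass. This loss therefore cannot tell which calls would hold. Fry, which tests whether a list's genes move one way on balance, called none of the 39 (lowest adjusted p 0.115).

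Of the 29 lists not called, several held members with large differences. ERK pathway output had a median of 1.65 (adjusted p = 0.191), with FOSL1 9.60-fold and ETV4 at least 5.47-fold higher. Among genes of other receptor kinases and ligands (median -0.57, adjusted p = 0.570), FGFR2 was at least 8.90-fold lower. Their median was 0.34 after quantile normalization, with probes chosen anew, and -0.65 in the authors' values, which kept the probes. Mesenchymal markers (median 0.82, adjusted p = 0.532) held SNAI1 at least 14.6-fold higher and SNAI2 at least 4.74-fold lower. Epithelial markers (0.50, adjusted p = 0.801) held CLDN4 at 13.0-fold higher, and basal keratinocyte genes had a median of 0.61 (adjusted p = 0.315). Type I interferon genes had a median of 0.93 (adjusted p = 0.130) and IFI27 was 7.43-fold higher. In the hypoxia list (0.029, adjusted p = 0.831) ANGPTL4 was 15.2-fold higher, and among NRF2 targets (0.19, adjusted p = 0.746) SLC7A11 was 5.76-fold lower. In the Notch list (0.054, adjusted p = 0.817) LFNG was 10.2-fold lower and HES4 6.53-fold higher. Integrins (0.95, adjusted p = 0.0552) held ITGB6 at least 7.21-fold higher (well above background on 1 control array), and WNT genes (0.54, adjusted p = 0.430) WNT7A at 7.52-fold. Collagens and laminins (0.74, adjusted p = 0.337) held COL12A1 at 4.78-fold lower. After normexp correction the mean log2 differences were 1.65 for ITGB6, 2.70 for SNAI1, -1.48 for SNAI2, 1.44 for ETV4 and -2.33 for FGFR2. Each was smaller in size than the bound given here. None of these members passed 0.05 over all genes. Adjusted over the list alone, 5 interferon genes, 3 WNT genes and 2 integrins were higher, and 4 Notch genes were higher and 1 lower. The receptor kinase list had 3 higher and 2 lower, collagens and laminins 4 higher and 2 lower, mesenchymal markers 1 each way, and the basal keratinocyte and hypoxia lists 1 higher each and the NRF2 list 1 lower. Some of these lists were called under other settings: integrins higher in 6 of 16, among them 4 of the 6 scalings (adjusted p 0.0112 to 0.0494), ERK output higher after median centring (0.0222) and on spike-in scaling (0.0140), and interferon genes higher after median centring (0.0230) and without SAS (0.000638). Basal keratinocyte genes were called higher without HSC3 (0.0145), and receptor kinase genes (0.0495) and NRF2 targets (0.0319) lower with no filter.

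The remaining lists had medians of 0.94 for checkpoint and NK ligands (adjusted p = 0.138), 0.44 for cholesterol genes (adjusted p = 0.620), 0.10 for fatty acid synthesis (adjusted p = 0.806) and -0.75 for drug efflux and metabolism (adjusted p = 0.191). S phase genes had -0.18 (adjusted p = 0.0785), p53 targets 0.45 (adjusted p = 0.806), apoptosis regulators 0.54 (adjusted p = 0.648) and TGF-beta targets 0.18 (adjusted p = 0.745). Components of the RAS, RAF, PI3K and AKT pathways had 0.0042 (adjusted p = 0.745), YAP and TEAD targets 0.36 (adjusted p = 0.884) and stem cell genes 0.24 (adjusted p = 0.883). Nuclear genes of the respiratory chain had 0.39 (adjusted p = 0.166), keratinocyte differentiation genes 0.13 (adjusted p = 0.801), fibroblast markers -0.054 (adjusted p = 0.810) and endothelial markers 0.52 (adjusted p = 0.532). For RAS and AKT components, hypoxia, NRF2, YAP and keratinocyte differentiation genes the median lay above 0 while camera's direction was lower, and the mean of the fibroblast markers was 0.058 against their negative median. Adjusted over the list alone, 2 checkpoint and NK ligands, 3 apoptosis regulators and 1 endothelial marker were higher. Under other settings S phase genes were called lower in 5 of 16, among them without HSC3 (adjusted p = 4.99e-06), and checkpoint and NK ligands higher after median centring (0.0432) and on spike-in scaling (0.0321). Drug efflux genes were called lower with no filter (0.0319) and on spike-in scaling (0.0321), and RAS and AKT components lower with no filter (0.0319). Keratinocyte differentiation genes were called lower without SAS (0.00636) and higher without HSC3 (0.00158).

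Within lines, Sa3 had the fewest genes past 2-fold, 2325 at least 2-fold higher and 1981 lower. Among genes well above background on both arrays of a line, the highest in Sa3 next to TXNIP were ANGPTL4 (33.5-fold), SAA2 (32.7-fold), the cortisol-producing enzyme gene HSD11B1 (32.1-fold) and C10orf105 (28.4-fold). Of genes well above background on 1 array of the 2, IRX1 was at least 34.6-fold and C1orf21 at least 24.8-fold higher. The cytokine receptor gene IL20RB was 21.1-fold lower, ABCA12 17.6-fold, BDH1 15.4-fold, ZBED10P 14.4-fold and VAV3 13.3-fold. TENM2 was at least 15.2-fold and TMEM200A at least 10.2-fold lower. A second TENM2 probe differed by -3.11 log2 units in Sa3, less than this bound. In SAS, 5134 genes were at least 2-fold higher and 3603 lower. CRCT1, a gene of the epidermal differentiation region, was 236-fold higher, the heat shock gene HSPA6 189-fold, the sterol synthesis gene MSMO1 132-fold and FOS 105-fold. The hair keratin gene KRT34 was at least 255-fold, CCL26 at least 155-fold and IL13RA2 at least 94.7-fold higher. DDX28 was 62.6-fold lower, CBS 42.5-fold, PDE5A 39.1-fold, HPS6 37.8-fold and HEG1 33.8-fold. BEX2 was at least 70.9-fold, BTG3 at least 50.2-fold and CYREN at least 34.1-fold lower.

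In HSC3, 4917 genes were at least 2-fold higher and 3804 lower. VIM, the mesenchymal intermediate filament gene, was 348-fold higher there, while its log2 difference was -2.33 in Sa3 and -1.34 in SAS. SRPX2 was 224-fold, the protease inhibitor gene CST6 197-fold and CSF2 159-fold higher. The cytokine gene IL24 was at least 1947-fold, LSP1P5 at least 329-fold and SNURF at least 230-fold higher. NUPR1 was 597-fold lower, LGALS7 (galectin-7, of stratified epithelium) 301-fold, the glutathione peroxidase gene GPX2 216-fold, SPON2 161-fold and UNC5B-AS1 140-fold. ALDH3A1 was at least 584-fold, IGFBP2 at least 360-fold and TENM2 at least 262-fold lower. In HSC3 the second probes of IL24 (10.6 log2 units), LSP1P5 (3.58), ALDH3A1 (-8.13) and TENM2 (-6.46) differed by less than these bounds. These are single arrays. For a probe with the median spread between replicate spots, the technical half-width (95%) of such a difference was 0.15 to 0.19 log2 units over the arrays, which covers spot error only. It is wider for other probes, since the spot SD at the 95th percentile of probes reached 0.28. The counts moved with the scaling, to 865 higher and 4684 lower in Sa3, 416 and 12948 in SAS and 2319 and 6470 in HSC3 on spike-in scaling.

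The gene lists differed in how they behaved from line to line. NF-kB and inflammatory cytokine genes had medians of 0.995 in Sa3, 1.06 in SAS and 3.998 in HSC3, each above the 99th percentile of 10000 random lists matched on expression. Class I antigen presentation genes had 1.45, 0.92 and 2.51, with SAS at percentile 80.1, inside the central range of those lists. Mitosis genes had 0.79, 0.44 and 4.10, with SAS at percentile 93.8. ATF4 genes lay at percentile 0.03 or below in each line, with medians of -0.79, -0.41 and -1.17. Endoplasmic reticulum chaperones lay at 0.13 or below, with medians of -1.40, -0.14 and -0.10. In SAS and HSC3 they were thus low mainly against the random lists, whose medians were 0.62 and 0.60. Keratinocyte differentiation genes had a median of 2.24 in SAS (percentile 100) and -2.77 in HSC3 (percentile 0), with KRT6A at 3.54 in SAS and -2.40 in HSC3. Basal keratinocyte genes had 2.19 in SAS and -0.38 in HSC3. S phase genes had 1.24 in HSC3 (percentile 99.98), -1.20 in SAS and -0.58 in Sa3 (both percentile 0). YAP and TEAD targets had 1.32 in HSC3 and -0.85 in SAS, with CCN1 at 7.09 and -1.37. These differences between lines were not tested. Ribosomal protein and glycolysis genes lay between percentiles 40.5 and 96.8 in every line, and such highly expressed random lists themselves had medians above 0.

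**Figure D3:**
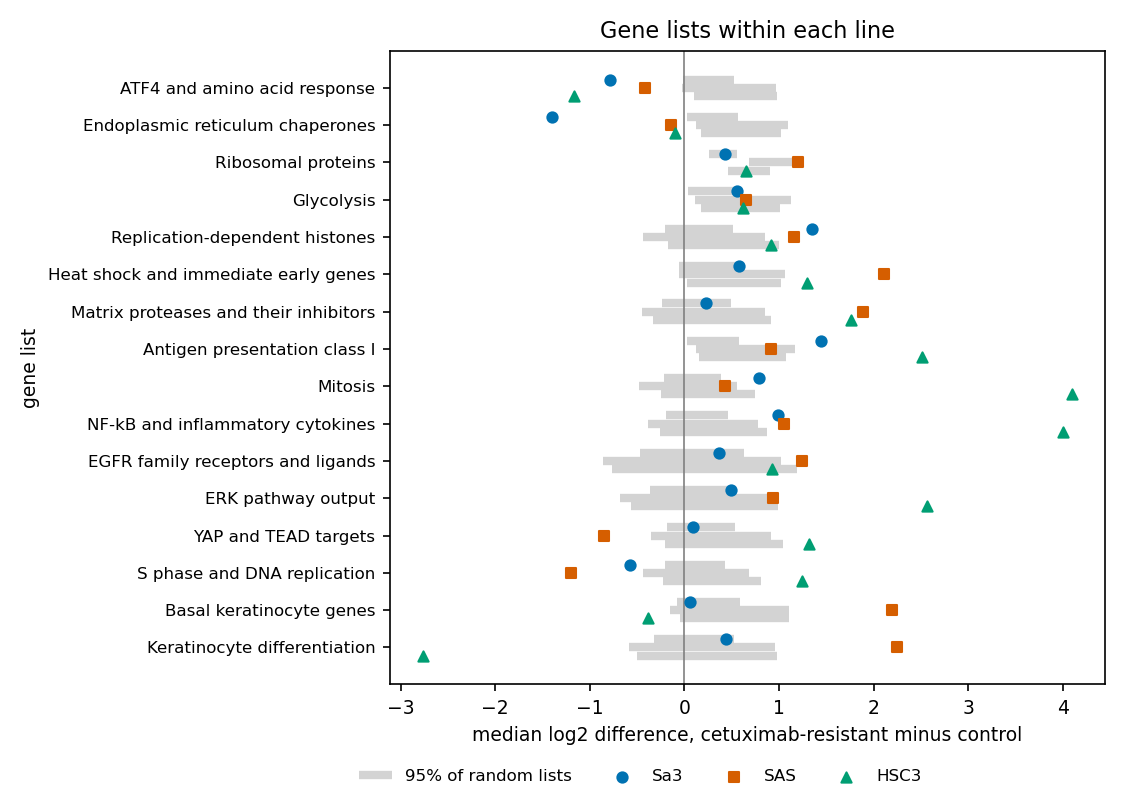
Median log2 difference between the resistant and the control array within each line (symbols) for the 10 gene lists called across lines and 6 others; grey bars hold 95% of random lists of the same size matched on expression. Keratinocyte differentiation genes lie at 2.24 in SAS and -2.77 in HSC3, on opposite sides of 0.

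Across genes, the lines' log2 differences correlated with Pearson r of 0.514 between Sa3 and SAS, 0.495 between Sa3 and HSC3 and 0.439 between SAS and HSC3 (Spearman 0.543, 0.523 and 0.471); genes are not independent replicates. Unlike the counts within lines, the overlaps cover all 18508 genes, also those well above background on neither array of a line. SAS and HSC3 shared 2755 genes at least 2-fold higher, against 1617 for independent lists of the sizes found over all genes, and 1820 lower, against 741. For Sa3 and SAS the shared counts were 1475 and 1157 (700.4 and 386 for independent lists), and for Sa3 and HSC3 1504 and 1279 (709.5 and 408). Levels also reflected the line. Cell line took 49.5% of the sum of squares over genes, condition 31.7% and the remainder 18.8%. No gene differed between the lines at adjusted p 0.05 in limma's F test, and 294 did at 0.1. The HSC3 resistant array correlated more closely with the resistant arrays of SAS (r = 0.898) and Sa3 (r = 0.888) than with its own control (r = 0.839). The SAS resistant array too correlated more closely with that of HSC3 (r = 0.898) than with its own control (r = 0.878), whereas the Sa3 resistant array correlated at 0.947 with its own control.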

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

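The values below were flagged because a gene list moved in opposite directions in 2 lines, outside the central range of matched random lists in both. The differences between lines were not tested, since each line has 1 array per condition. Median log2 differences differed by 5.01 between SAS and HSC3 for keratinocyte differentiation genes, 2.58 for basal keratinocyte genes (both higher in SAS) and 2.17 for YAP and TEAD targets (higher in HSC3). S phase genes were higher in HSC3 than in Sa3 by 1.82 and than in SAS by 2.44. The tests of exchanged labels, of labelling and of leukocytes below were chosen after the values they use were seen; the others were written before.

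The HSC3 resistant array correlated more closely with the SAS resistant array than with its own control, and the SAS resistant array more closely with the HSC3 resistant array (r = 0.898) than with its own (r = 0.878). An exchanged or wrong line label was argued against by line-restricted genes, at least 8-fold above or below the other 4 arrays. The HSC3 resistant array shared 37 of these with the HSC3 control, 2 with the SAS control and 0 with the Sa3 control, and the SAS resistant array shared 45 with the SAS control and 4 with the HSC3 control. Cells of SAS mixed into the HSC3 resistant sample at a share above 5% were argued against as well, because 36% of 25 genes restricted to SAS lay in the HSC3 resistant array below 5% of their SAS level. The median of the 25 was 9.8% of that level, and some, such as IL24 (1038%), lay above it. HSC3 cells mixed into the SAS resistant sample stay open: 55.6% of the genes restricted to HSC3 lay below 5% of their HSC3 level there, but these were 9 genes, fewer than the 10 required beforehand. Dim probes do not account for it either: over the 12934 genes well above background on all 6 arrays, the correlation was still higher with the SAS resistant array, by 0.0512. Over these genes the HSC3 resistant array correlated at 0.914 with the Sa3 and 0.913 with the SAS resistant array. The SAS and HSC3 resistant arrays had the lowest 75th percentiles of signal (79.1 and 92.3). An effect of weak signal shared by both was not tested and stays open. So do a smaller share of other cells and a response shared by resistant cells, which was not tested.

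Endogenous signal was lower against the spike-ins on each resistant array, by -0.58 (Sa3), -2.00 (SAS) and -0.81 (HSC3) log2 units. Weaker labelling, hybridisation or scanning would have lowered the spike-ins too, and their change was at most 0.226 of that of the 75th percentile. RNA degradation with loss of 5′ sequence would have lowered 5′ probes more than 3′ probes. This was looked at over 1721 transcripts with 2 probes, both well above background on every array. There the 5′ probe was instead higher relative to the 3′ probe in resistant cells. The smallest line median was 0.122 (Sa3; 95% bootstrap interval 0.101 to 0.139). Transcripts whose 5′ probe fell to background on a resistant array were left out by this choice. The values thus show no 5′ loss among the transcripts kept, and degradation beyond them stays open. Less input RNA or less mRNA per total RNA was not tested and stays open, as does a biological change in mRNA content.

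Antigen presentation and inflammatory lists were higher in resistant cells. RNA of leukocytes could raise both, and the values leave this open. Of the 9 of 16 leukocyte markers well above background on all 3 resistant arrays 1, CD68, was at least 2-fold higher in every line, and PTPRC was well above background on 2 control arrays and 1 resistant array. The markers went both ways: LAPTM5 differed by -0.64 in Sa3, 3.64 in SAS and -0.34 in HSC3, CSF1R by -4.02 in SAS and 4.76 in HSC3, and HCLS1 by 0.49, 4.68 and 2.31. As a list they lay at percentiles 88.5 (Sa3), 99.05 (SAS) and 99.97 (HSC3) of matched random lists and were called higher under 5 of 6 other scalings. As 8 of the 9 were well above background on all control arrays too, a small share would be hidden. This criterion replaced a first one, the number of the 16 markers well above background on all resistant arrays (9), which did not decide the question. A response of the tumour cells themselves stays open as well.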

How the results depend on the processing

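Signal over background limits genes low in resistant cells, since 38.7% to 48.5% of probes were well above background there. It bears on dim genes that came out higher too. The lowest value well above background rose from control to resistant arrays, from -4.50 to -3.55 (Sa3), -4.07 to -2.11 (SAS) and -3.53 to -2.18 (HSC3). Probes near background can thus lie higher on resistant arrays on this scale. With no filter the median gene lay at 0.90, and with the filter on all 6 arrays at 0.32. Spike-in scaling and the 75th percentile of detected probes were chosen after seeing the data. Scalings move the centre: the median gene lay at 0.25, but at -0.01 after quantile normalization, -0.42 after median centring and -0.88 on spike-in scaling, and at 0.22 after normexp correction. The causes of other changes were not tested.

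Genes past adjusted p 0.05 (higher, lower) numbered 0 and 0, but 41 and 65 after normexp correction, 136 and 3336 on spike-in scaling, 389 and 493 with a random block and 646 and 624 at adjusted p 0.1. With no replicate block (cell line term left out) they were 0 and 0, and without Sa3, SAS or HSC3 0 and 0 each time. Without the block, 6 lists were higher and 2 lower: glycolysis and matrix proteases were no longer called (adjusted p = 0.0661 each), no other list call ended, and no called list turned.

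Genes 2-fold changed in every line (1034, 871) became 649 higher after quantile normalization, 656 in the authors' values, 657 with the 75th percentile of detected probes, 283 and 1943 after median centring, 332 and 407 after normexp correction, 628 and 310 with the all-array filter, 4685 higher with no filter, and 81 and 3038 on spike-in scaling. Leaving out a line gave 1475 to 2755 higher and 1157 to 1820 lower, as fewer lines must pass.

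Within Sa3 they became 1380 and 3165 after median centring, 1173 and 1036 after normexp correction, 1432 and 818 with the all-array filter, and 865 and 4684 on spike-in scaling. In SAS they became 1587 and 8006 after median centring, 1925 lower with the all-array filter, and 416 and 12948 on spike-in scaling. In HSC3 they became 2591 and 6039 after median centring, 2979 and 2308 after normexp correction, 1746 lower with the all-array filter, and 2319 and 6470 on spike-in scaling.

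Gene lists called (8 higher, 2 lower) were 5 higher after normexp correction, 1 and 7 with no filter, and 0 and 0 with an estimated correlation or fry. Leaving out a line gave 5 to 8 higher and 1 to 3 lower. Ribosomal proteins turned lower after quantile normalization (adjusted p = 0.418) and in the authors' values (0.427). In SAS on spike-in scaling medians turned to -0.76 for EGFR family genes, -1.06 for ERK output, -0.94 for NF-kB genes, -0.62 for Notch, -0.11 for matrix proteases, -0.93 for collagens, -0.76 for integrins, -0.84 for checkpoint ligands, -0.84 for histones and -0.69 for leukocyte markers, and in Sa3 to -0.0082 for heat shock genes. ERK output in SAS turned to -0.073 after median centring. Nuclear respiratory chain genes in SAS turned to -0.36 (quantile), -0.80 (median centring), -0.33 (normexp), -0.028 (detected probes) and -1.79 (spike-ins).

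EGFR turned to -0.078 on spike-in scaling and stayed positive elsewhere (highest 1.32), with limma adjusted p from 0.121 to 0.952. In the authors' values, which kept its probe, DDRGK1 stayed at 4.01. It turned to -0.87 (quantile) and -0.94 (normexp), where the probe was chosen anew. Of 391 alternative values of the named genes other than EGFR, these 2 turned, 337 kept direction and side of the threshold and 52 passed it. Correlations moved to 0.565 (normexp), 0.564 (all-array filter) and 0.449 (no filter) for Sa3 and SAS, and 0.419 (no filter) for Sa3 and HSC3. Genes different between lines (0) were 314 after normexp correction, 21 with the all-array filter, 327 with no filter, 69 with the mean of probes, 1847 on spike-in scaling and 294 at adjusted p 0.1.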

Other observations

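The 10 gene families tried and the tests of TXNIP, of ZNF genes and of the count at adjusted p 0.05 were chosen after their results were seen. The values below are medians over members in Sa3, SAS and HSC3, in log2 units. The 12 genes encoded by the mitochondrial genome had -0.65, -2.20 and -1.22, at percentile 0 of matched random lists in every line, led by COX3 (mean difference -2.77) and CYTB (-2.49). The nuclear genes of the respiratory chain had 0.36, 0.20 and 0.74 on the same arrays, at percentiles 57.5, 1.2 and 76.5. In SAS they too thus lay low among matched random lists, and their median there turned negative under other scalings. The 12 HLA class II genes measured had 1.69, 1.15 and 2.51, with HLA-DPB1 at 2.81, 2.75 and 2.58 and HLA-DRB1 at 1.99, 1.27 and 6.69. Cancer-testis genes of the MAGE, PAGE, XAGE, GAGE and SPANX families (12 genes) had 1.07, 1.78 and 3.40. PAGE2B had a mean difference of 3.64 and PAGE2 of 3.51 (each well above background on 1 control and 3 resistant arrays), and SPANXB1 was well above background on no control array and on all 3 resistant arrays. The 228 small nucleolar and Cajal body RNA genes had 0.49, 1.61 and 0.62, each at percentile 100, with 29 at least 2-fold higher and 0 lower in every line. The DUSP phosphatase genes, feedback inhibitors of MAP kinases, had 0.36, 1.03 and 0.07, with DUSP1 at 0.48, 4.03 and 5.09. Over the 6 scalings the medians of the mean differences stayed positive for the HLA class II and cancer-testis families and negative for the mitochondrial genes, and turned to -0.21 (small nucleolar RNAs) and -0.53 (DUSP genes) on spike-in scaling and -0.072 (DUSP genes) after median centring. The other families tried were keratins, SERPINB genes, claudins, solute carriers and ZNF genes.

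Among transcripts with both probes well above background on every array, probes nearer the 5′ end were higher relative to 3′ probes in resistant cells. The median gap was 0.12 in Sa3, 0.30 in SAS and 0.23 in HSC3. The gap grew with the genomic distance between the probes, from 0.03, 0.01 and 0.10 under 1 kb to 0.25, 0.74 and 0.39 over 10 kb. Of 4 named genes with disagreeing probes that were looked at after their values were seen, OSMR, NEDD9 and DDRGK1 followed that order and EGFR did not. The 5′ probe of OSMR (chromosome 5, 38886589 to 38886648) had a mean difference of 4.89 and the 3′ probe (38933387 to 38933446) -0.31. For NEDD9 the values were 4.98 and -0.59, for DDRGK1 4.26 and -0.79. In EGFR the probe at 55224558, which the files annotate as another transcript variant, had 2.63, that at 55231446 -0.51 and that at 55274841, used above, 1.05. Gene-level values for such genes therefore rest on 1 probe, and whether the probes differ because they measure different parts of the transcript was not tested.

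The 397 genes named ZNF, many of which encode short-lived transcripts, had medians of -0.19, -0.76 and -0.64. The highest of the 3 percentiles among matched random lists was 0, with 49 ZNF genes at least 2-fold lower and 3 higher in every line. The median of the mean differences was -0.54, and -0.099 after normexp background correction. These values restate that the genes were low and do not test whether a loss of short-lived transcripts lies behind it. Other genes with short-lived transcripts went both ways, with mean differences of 2.72 for FOS (-0.37 in Sa3), 2.04 for IER3 and 3.27 for TNF, but -0.61 for EGR1 and -0.81 for MYC, and EGR2 at least 1.23-fold lower. RNA half-lives were not measured, so this stays open.

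TXNIP and ARRDC4 (3.003, 3.49 and 4.11 in the 3 lines) are targets of the glucose-sensing factors MondoA and ChREBP. Of 4 other targets considered jointly (ARRDC4, KLF10, PFKFB3 and HK2), the median of the mean differences was 1.36, but the members went both ways, from 3.53 (ARRDC4) to -0.77 (HK2), and none passed adjusted p 0.05. Whether the activity of these factors was raised stays open. Culture conditions at harvest, such as glucose, cell density or the presence of cetuximab, could differ between control and resistant cells and were not tested.

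The 6 arrays allow 10 splits into 3 and 3, so a share under 0.05 cannot be reached. Only 4 of them part all 3 pairs, as the real one does; the other 6 part 1 pair and rest on it alone. At adjusted p 0.1 the real split gave 1270 genes and the highest of the others 0, so 1 of 10 splits, and 1 of the 4, gave as many. The real labels themselves gave 0 at 0.1 after quantile normalization, in the authors' values, with the mean of probes, without the block, and without Sa3 or SAS, where other splits were not run. At 0.05 all 10 splits gave 0. For gene lists called with a preset correlation, 2 of 10 splits gave as many as the real 10, both among the 4, the highest other being 13, from the split that exchanges the labels of SAS. The count of list calls thus does not set the real labels apart. The other splits still set control against resistant arrays within lines, so their calls can come from real differences there. They cannot show whether the preset correlation gives calls where there are none.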
